A study of Manihot esculenta with 18 samples.

How the data were processed

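Leaf RNA of 2 cassava cultivars, Huay Bong 60 (HB60) and Hanatee (HN), was measured on 18 1-colour Agilent arrays, 3 for each of 6 groups: control, 24 h and 72 h after stem inoculation, in each cultivar. Per the labels, plants were 8 weeks old, spores were applied to punctured stems, controls received sterile water, and the third fully expanded leaf was taken. The labels also call the controls untreated, state no harvest hour for them, and mention drought in the extraction protocol.

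Per the file headers, the authors scanned the arrays in 1 colour and quantified them with Agilent Feature Extraction 10.7.3.1, and the deposited scanner files hold intensity for each spot, background-subtracted within the array and not normalized between arrays. The deposited table of the series holds log2 values that the authors made. How they normalized it is not given in the sources used here. Its 59135 entries per array have nearly the same distribution on all arrays (medians 3.77 to 3.78) and a rank correlation of at least 0.99997 with the scanner values.

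Of 61657 cassava spots per array, repeat spots of 2578 probes were averaged, which left 59079 probes, each with its own sequence ID. The files pair 44451 of them with a description, mostly of a related Arabidopsis gene, and 14628 are called Unknown. Of the IDs 0 matched the reference file of cassava genes, so no genome position is given. No spot was saturated, and 0 to 15 spots per array marked as irregular by the extraction software were left out. The log2 of the processed signal was set relative to the array's 75th percentile. The 30080 probes well above background, by the extraction software's mark, on all 3 arrays of at least 1 group were tested, and 21009 were well above background on all 18 arrays.

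All 18 arrays were fitted together with limma 3.58.1 in R 4.3.3, with 6 group means, 12 residual degrees of freedom and 3.63 prior degrees of freedom from the moderated variance. A call is a Benjamini-Hochberg adjusted p under 0.05. The 9 comparisons were infected against control at each time in each cultivar, 72 h against 24 h in each, the difference of the responses of the cultivars at each time, and HB60 against HN controls. Gene lists, fixed from words in the descriptions, were tested with camera at a preset correlation of 0.01 where at least 5 probes were measured, then with an estimated correlation and with fry. A camera call compares a list with other probes, and fry tests whether a list's probes move one way on balance. The lists were pathogenesis-related proteins, phenylpropanoid and lignin, class III peroxidases, flavonoid, salicylic acid, jasmonate, ethylene, abscisic acid and drought, auxin, WRKY, NAC, resistance proteins, receptor kinases, cell wall, redox and detoxification, heat shock, photosynthesis, clock, cell cycle and histones, senescence, protease inhibitors, calcium signalling, lipid transfer, cytosolic ribosomal proteins, epidermis and wax, vascular and stem, and reference genes; the cyanogenic list had no probe. A hypergeometric test of called members was added after the data were seen. It treats probes as independent and does not measure variation between plants. Tables and figures were made with the R packages data.table (version 1.17.8) and jsonlite (2.0.0), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

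Lists, comparisons and the rule for named genes were fixed before the data were examined. Among described probes, the rule names the 6 largest increases and 6 largest decreases among calls whose groups do not overlap, up to 3 called members of each list, 2 members of a list that camera calls without a called member, the 6 smallest p where there are fewer than 10 calls, and the clock list. The alternatives were quantile normalization, normexp background with an offset of 50, the authors' values, filters on dim probes, slide as a fixed or random block, fits within one slide, a replicate block, fits of only the groups compared, an intensity trend with robust variance, array weights, a 2-fold minimum, leaving out each array in turn, and other list tests. A percentile over detected probes and leaving out a pair of arrays together were added after the data were seen. Shared controls were simulated 500 times with unchanged groups.

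The fit was tested on simulated data with 5 simulations of 200 changed probes among 30056. It recovered 21.6% of probes changed by a log2 of 1, 84.4% at 2, 96% at 3 and 98% at 4, with 4.64% false calls. The simulated noise was independent between probes, of equal spread on all arrays and free of slide effects. These rates may therefore not hold for the real arrays. The number of arrays limits the precision.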

Results

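Gene expression was measured in leaves of 2 cassava (Manihot esculenta) cultivars, Huay Bong 60 (HB60) and Hanatee (HN), after fungal spores were applied to punctured stems. The fungus was Colletotrichum gloeosporioides f. sp. manihotis, which causes cassava anthracnose. Each cultivar had a control group given sterile water and groups sampled 24 h and 72 h after inoculation, with 3 arrays per group and 18 arrays in all. The labels call the replicates independent biological samples and do not state the hour at which control leaves were taken. Each 1-colour array carried 59079 cassava probes, 1 per sequence ID, and 30080 of them were tested because they lay well above background on every array of at least 1 group. The 75th percentile of the signal ran from 44.8 in HN control replicate 2 to 171 in HN 24 h replicate 3, and 40.6% to 56.7% of an array's probes were well above background. The number of arrays limits the precision of every value.

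The arrays lay on 3 slides. Slide 1 held the HB60 24 h group and 2 HB60 controls, slide 2 held the other HB60 control, the HB60 72 h group and HN 24 h replicate 1, and slide 3 held all remaining HN arrays. In fits with slide as a block, the HB60 72 h comparisons within that cultivar and the 72 h response difference are linked only through HB60 control replicate 3. The blocked control comparison is linked only through that array and HN 24 h replicate 1. These blocked values therefore rest on 1 or 2 arrays, and they are given only as measured. For the HN 24 h changes, slide as a block and the fit within slide 3 give the same sizes. Both leave out HN 24 h replicate 1, the only HN array on slide 2, so they are not separate checks. The HB60 24 h changes likewise leave out HB60 control replicate 3 in both. The first principal component carried 41.3% of the variance and separated the cultivars, and the second carried 16.8%. HN 24 h replicate 1 (mean r = 0.931 across probes) and HN control replicate 2 (0.940) correlated least with their own groups. Levels are log2 signals relative to the array's 75th percentile, as mean ± SD with n = 3, and changes are log2 differences ± SE with limma's Benjamini-Hochberg adjusted p. Where a probe was not well above background on any array of the dimmer group, the change is a bound, "at least N-fold". The bound sets the brighter group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. Gene names are the descriptions paired with each sequence ID in the files, mostly those of Arabidopsis relatives, and several IDs with 1 description may stem from 1 gene.

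**Figure D1:**
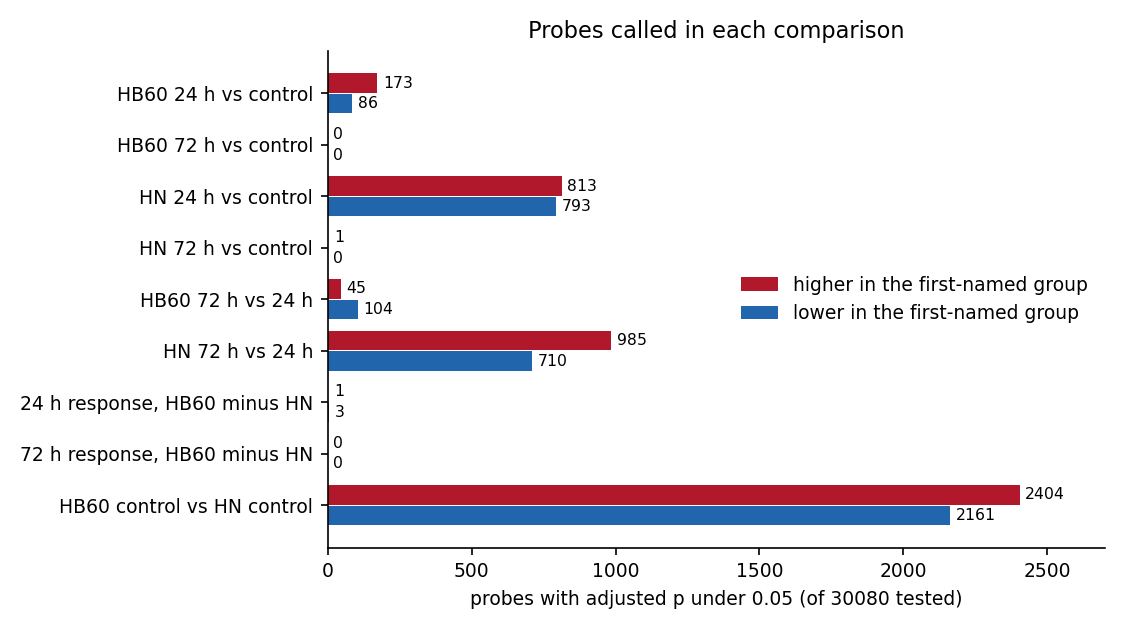
Bars give the number of probes per comparison with an adjusted p under 0.05, higher or lower in the first-named group, on a linear axis. The control comparison between cultivars has 2404 and 2161 such probes, HN at 24 h has 813 and 793, HB60 at 24 h has 173 and 86, and the 72 h comparisons with controls have 1 or 0.

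The first comparisons ask which leaf genes change after stem inoculation in each cultivar. In HB60 leaves 24 h after inoculation, the largest increases included cell wall, auxin and abscisic acid genes. Xyloglucan:xyloglucosyl transferase 33, an enzyme that remodels wall xyloglucan, rose at least 13.2-fold by probe 454_Contig07438 (adjusted p = 1.79e-05). A second probe of that name, 454_GHRYMOR02GYMU0, rose from -2.58 ± 1.89, well above background on 2 control arrays, to 2.90 ± 0.32 (adjusted p = 0.00171). Probes of the SAUR-like family, small auxin-induced growth proteins, rose at least 11.7-fold (JGIv7_cassava4.1_026012m, adjusted p = 0.000205) and at least 4.52-fold (454_GHRYMOR02GC80T, adjusted p = 0.000113). PYR1-like 4, an abscisic acid receptor, rose at least 10.5-fold by EST_CK652606 (adjusted p = 0.000211), and EST_Contig08257 of the same name rose by 2.38 ± 0.42 (adjusted p = 0.0149). A LEA3 family gene, of proteins that protect drying tissue, rose by 3.35 ± 0.34 from 2.01 ± 0.10 to 5.36 ± 0.41 (JGIv7_cassava4.1_020224m, adjusted p = 0.000205).

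Of 30080 probes, 259 were called in this comparison, 173 higher and 86 lower, and 228 of them by at least 2-fold. Of 264 cell wall probes, 12 rose, none fell and 252 did not pass, and camera used the 263 with a value on every array. Adjusted over the list alone, 23 rose and 2 fell. Chance would give 1.52 increases (adjusted p = 1.28e-06, a hypergeometric test added after the data were seen). That test, here and below, treats probes as independent. Several IDs of 1 gene, or genes that vary together, would make its p-values too small. Expansin-like A1 (EST_DR085849), of a family that loosens walls, rose by 2.85 ± 0.34 from -1.55 ± 0.77 to 1.30 ± 0.20 (adjusted p = 0.00119). The list's mean change was 0.36 (camera adjusted p = 0.000155; adjusted p = 0.879 with an estimated correlation). It was 0.15 with slide as a block (adjusted p = 0.0918) and 0.15 within slide 1 (0.0683). Of the 10 splits of the arrays of this comparison, 8 gave at least as many lists called by camera, the real split included. In every comparison some other grouping gave as many, so chance cannot be excluded for the camera counts here and below. Of 148 auxin probes 5 rose and 143 did not pass, against 7 higher and 2 lower when adjusted over the list alone. The mean change was 0.18 (camera adjusted p = 0.0301; adjusted p = 0.879 with an estimated correlation). It was 0.17 (adjusted p = 0.0529) with slide as a block and 0.17 (0.0683) within slide 1. Among 99 abscisic acid and drought probes 3 rose, 2 fell and 94 did not pass, and adjusted over the list alone 4 rose and 2 fell.

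Respiratory burst oxidase D, which makes superoxide at the plasma membrane, rose by 2.15 ± 0.44 (EST_DV442413, adjusted p = 0.0334) and 1.73 ± 0.38 (EST_Contig08387, adjusted p = 0.0474). Thioredoxin H-type 7 (EST_Contig07089), well above background on 2 arrays at 24 h and on no control array, completed the 3 of 243 redox probes that rose, while 240 did not pass (4 higher adjusted over the list alone). Chitin elicitor receptor kinase 1, which binds fungal chitin, fell from 0.05 ± 0.23 to -1.46 ± 0.53 (454_Contig02835, adjusted p = 0.0388), whereas leucine-rich repeat kinase EST_CAS01_047_A16.f, above background on 1 control array, rose by 3.66 ± 0.49, and EST_Contig12915 rose at least 1.94-fold. The 338 other receptor kinase probes did not pass, and adjusted over the list alone 5 rose and 1 fell. A TIR-class resistance gene (454_Contig05899) rose by 1.97 ± 0.33 (adjusted p = 0.0103), the only 1 of 88 in its list with either adjustment. WRKY 21 and WRKY 27, defence-related transcription factors, rose among 77 WRKY probes, by 1.55 ± 0.26 for WRKY 21 (JGIv7_cassava4.1_032017m) and at least 1.95-fold for WRKY 27 (JGIv7_cassava4.1_008781m). Adjusted over the list alone 2 rose and 1 fell. Ethylene responsive element binding factor 1 (EST_Contig14556) rose by 1.35 ± 0.29, alone among 37 ethylene probes with either adjustment, and senescence-associated gene 21 (EST_Contig15105) by 2.02 ± 0.33, alone among 39 (2 adjusted over the list alone).

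Of 221 heat shock probes 8 fell, none rose and 213 did not pass, and adjusted over the list alone 15 fell; with normexp 3 fell. They include heat shock protein 101 (454_Contig11535), a disaggregating chaperone, lower at 24 h by at least 2.21-fold (adjusted p = 0.0243), and DNAJ protein 454_Contig07335, which fell by 1.94 ± 0.43 (adjusted p = 0.0489). Calcium probes went both ways, 3 higher and 2 lower of 217 (11 and 8 adjusted over the list alone). Among 73 epidermis and wax probes 2 rose, both 3-ketoacyl-CoA synthase 10, an enzyme of very-long-chain wax lipids, by 1.41 ± 0.23 (EST_Contig15193) and 1.33 ± 0.24 (454_GHRYMOR02IUG7D). Of that list 4 rose adjusted over the list alone. COBRA-like protein 1 accounted for the 2 of 32 vascular probes that rose (3 adjusted over the list alone), and tubulin alpha-5, 1.20 ± 0.24 by 454_Contig02403, for the 2 of 174 reference probes (2 adjusted over the list alone). No probe passed in the pathogenesis-related, phenylpropanoid, peroxidase, flavonoid, salicylic acid, jasmonate, NAC, photosynthesis, clock, cell cycle, protease inhibitor, lipid transfer or ribosomal lists by limma over all probes. Adjusted over each list alone, 1 phenylpropanoid probe rose and 1 ribosomal probe fell. Camera also called the receptor kinase (mean 0.18), epidermis and wax (0.19), reference (0.14), ethylene (0.25) and peroxidase (0.37) lists higher, each with adjusted p = 0.879 with an estimated correlation. With slide as a block their means were 0.20, 0.08, 0.06, 0.37 and 0.39, the same as within slide 1. The epidermis and wax (adjusted p = 0.0976), reference (0.241) and peroxidase (0.0529) calls were lost with the block, and only the peroxidase call was kept within slide 1 (0.0237). Camera called 3 lists only with slide as a block: cell cycle (mean -0.50, adjusted p = 0.0018; -0.23 without), WRKY (0.23, 0.0178) and resistance proteins (0.21, 0.0196). Within slide 1, which holds 2 of the controls, these 3 lists and flavonoid enzymes (-0.35, 0.0428) were also called. There 1 cell cycle probe rose and 14 fell of 121 (3.52e-08), and 7 WRKY, 5 peroxidase and 3 NAC probes rose. Array weights, here and below, were largest for HB60 control replicate 2 (8.03) and HN control replicate 3 (6.10). The other controls had 0.200 to 1.39, so weighted control means rest mostly on 1 array per cultivar. The count of 259 was 308 with slide as a block, 652 within slide 1, 7744 with array weights and 82 with no filter on dim probes. It was 103, 86 and 68 without HB60 24 h replicates 1, 2 and 3, 102, 45 and 149 without HB60 control replicates 1, 2 and 3, 390 without HN 24 h replicate 1, 431 without HN control replicate 2 and 170 without HN 72 h replicate 3.

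**Figure D2:**
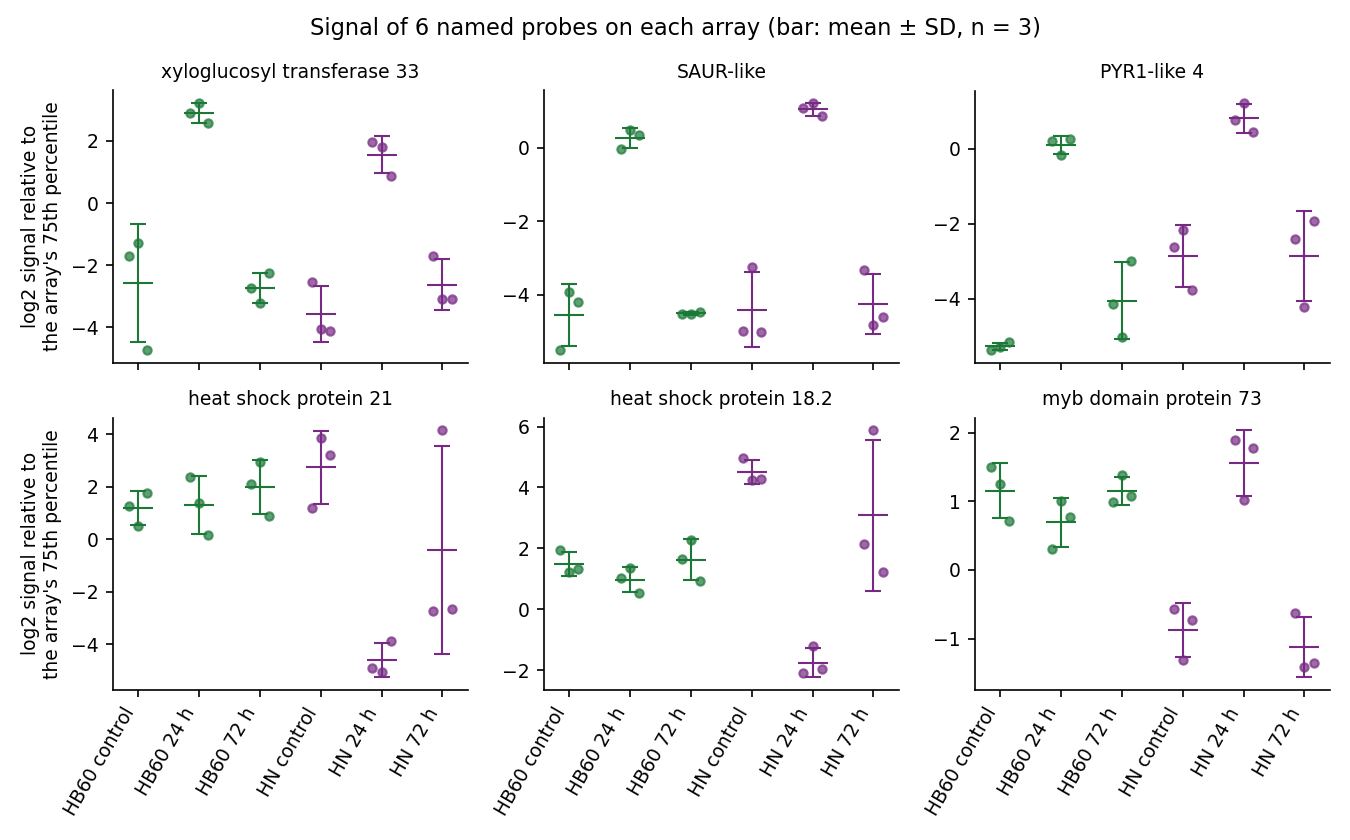
Points are single arrays and bars are mean ± SD (n = 3) of the log2 signal relative to the array's 75th percentile, for 6 named probes in the 6 groups. Xyloglucosyl transferase 33, the SAUR-like probe and PYR1-like 4 are high at 24 h in both cultivars, while the heat shock proteins are low at 24 h in HN and the HN 72 h arrays differ widely.

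At 72 h, no probe differed between HB60 infected and control leaves by limma, and 1047 had an unadjusted p under 0.05, where chance gives 1504. The smallest adjusted p was 0.999. None of the genes named at 24 h was called at 72 h. The LEA3 probe JGIv7_cassava4.1_020224m lay at 2.05 ± 0.70 against 2.01 ± 0.10 in controls, and senescence-associated gene 21 (EST_Contig15105) at 0.54 ± 0.59 against 0.57 ± 0.12. Quantile, normexp and the authors' values also gave a count of 0, slide as a fixed block gave 6, and array weights gave 2264. Camera called 3 lists higher, each with adjusted p = 0.943 with an estimated correlation: flavonoid enzymes, which make pigments and phenolic compounds (mean 0.42), jasmonate (0.22) and ethylene (0.24). Within slide 2, as with slide as a block, these means were 1.01, 0.16 and -2.46e-06, and no probe was called within slide 2. The jasmonate and ethylene calls were lost in both. That slide holds only 1 HB60 control, so these values, the 6 calls with the block and the 10 further lists that camera called only with the block rest on 1 control array. In the flavonoid list of 27 probes, a chalcone and stilbene synthase probe (454_F7JABCT02IHS4G) differed by 0.89 ± 0.31 (adjusted p = 0.999), and no member of any list passed over all probes or over its list alone.

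In HN leaves 24 h after inoculation, small heat shock proteins, chaperones that hold unfolding proteins, had the largest decreases, while auxin and cell wall genes were among the largest increases. Heat shock protein 21, a chloroplast chaperone, fell by at least 61.4-fold by EST_Contig12518 (adjusted p = 0.00604) and at least 50.1-fold by EST_Contig08630 (adjusted p = 0.00491). Heat shock protein 18.2 (EST_Contig05472) fell by 6.25 ± 0.80 from 4.50 ± 0.40 to -1.75 ± 0.48 (adjusted p = 0.000425). SAUR-like probes rose at least 12.4-fold (JGIv7_cassava4.1_026012m, adjusted p = 4.32e-05) and at least 6.01-fold (454_GHRYMOR02GC80T, adjusted p = 1.86e-05). A gibberellin-regulated family probe (JGIv7_cassava4.1_019838m) rose at least 11-fold and a phosphate-responsive 1 probe (EST_Contig09296) at least 14.8-fold. Xyloglucan:xyloglucosyl transferase 33 rose at least 3.96-fold by 454_Contig07438 (adjusted p = 4.56e-05).

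In total 1606 probes were called, 813 higher and 793 lower, and 1102 by at least 2-fold. Of 221 heat shock probes 35 fell, 2 rose and 184 did not pass. Adjusted over the list alone 41 fell and 7 rose. Chance would give 5.83 decreases if probes were independent (hypergeometric adjusted p = 4.37e-16). The list's mean change was -0.72 (camera adjusted p = 0.000379; adjusted p = 0.205 with an estimated correlation; fry adjusted p = 0.000396). It was -0.73 both with slide as a block (adjusted p = 0.0119) and within slide 3 (0.0139). The 35 probes fell by a median of 4.40, and 24 of them still passed without HN control replicate 2. Of 264 cell wall probes 25 rose, 10 fell and 229 did not pass (38 and 18 adjusted over the list alone), against 7.14 increases by chance (hypergeometric adjusted p = 1.83e-06). Expansin B2 (EST_FF536190), a wall-loosening protein, was among those that fell, by at least 3.57-fold. The cell wall mean was 0.31 (camera adjusted p = 0.0358; adjusted p = 0.947 with an estimated correlation), and 0.40 with slide as a block or within slide 3 (0.00202 and 0.00146). Of 148 auxin probes 10 rose, 2 fell and 136 did not pass (17 and 5 adjusted over the list alone). This balance did not hold with slide as a block, where 11 rose and 17 fell, or within slide 3 (6 and 5).

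Of 75 jasmonate probes 9 fell, none rose and 66 did not pass (19 lower adjusted over the list alone), where chance gives 1.98 decreases (hypergeometric adjusted p = 0.00211). Allene oxide synthase, which commits lipid peroxides to jasmonate synthesis, fell by 1.72 ± 0.40 from 4.73 ± 0.12 to 3.01 ± 0.59 (454_Contig12929, adjusted p = 0.0232). Of 5 probes with that description 4 fell, and these 4 of the 9 may measure 1 gene. The list's mean was -0.43 (camera adjusted p = 0.000379; adjusted p = 0.947 with an estimated correlation) and -0.47 with slide as a block or within slide 3 (0.00435 and 0.00146). Of 77 WRKY probes 2 rose, 5 fell and 70 did not pass (3 and 7 adjusted over the list alone; 2 and 2 with normexp). WRKY 21 (JGIv7_cassava4.1_032017m) rose by 2.55 ± 0.26. The list mean was -0.28 (camera adjusted p = 0.0388; adjusted p = 0.947 with an estimated correlation) and -0.40 with slide as a block or within slide 3. Of 99 abscisic acid and drought probes 5 rose and 8 fell (5 and 11 adjusted over the list alone; hypergeometric adjusted p = 0.0317 for the decreases), but camera did not call the list (adjusted p = 0.22). PYR1-like 4 rose at least 9.87-fold by EST_CK652606 (adjusted p = 0.00152) and the LEA3 probe JGIv7_cassava4.1_020224m by 2.79 ± 0.34 (adjusted p = 0.000280). Of 73 epidermis and wax probes 7 fell (7 adjusted over the list alone; 2 with normexp; hypergeometric adjusted p = 0.0280), among them GDSL lipase-like EST_Contig05385, by 1.44 ± 0.33. Camera did not call that list (mean 0.02, adjusted p = 0.99), and 39 of its 73 probes were higher at 24 h.

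Of 341 receptor kinase probes 12 rose and 8 fell (13 and 9 adjusted over the list alone; 8 and 8 with normexp), with leucine-rich repeat kinase EST_CAS01_047_A16.f higher by 3.50 ± 0.49 and above background on 2 control arrays. The TIR-class resistance gene 454_Contig05899 rose by 2.94 ± 0.33 from -1.76 ± 0.49 to 1.18 ± 0.75 (adjusted p = 0.000159). In that list 1 of 88 resistance probes was lower (1 higher and 0 lower adjusted over the list alone). Chitinase A (EST_Contig06167), which degrades fungal walls, rose from -1.84 ± 0.37 to 1.15 ± 2.20, well above background on 2 control arrays, in a pathogenesis-related list with 3 higher and 1 lower of 63 by either adjustment. Peroxidases had 3 higher and 2 lower of 58 by either adjustment, and redox genes 6 higher and 7 lower of 243 by either (6 and 6 with quantile normalization, 5 and 3 with normexp). With slide as a block peroxidases had 4 higher and 11 lower, redox genes 11 and 34, and pathogenesis-related probes 3 and 6. Within slide 3 the counts were 2 and 5, 4 and 5, and 1 and 4 in that order. Ascorbate peroxidase 1 (454_GHRYMOR02FVHJR), which removes hydrogen peroxide, fell by 4.31 ± 0.88 with 1 array above background at 24 h. All 7 called calcium probes of 217 rose (6 adjusted over the list alone), with calmodulin-like 11 (JGIv7_cassava4.1_018372m) up by 1.90 ± 0.33. With slide as a block, however, 8 calcium probes rose and 19 fell, and within slide 3 the counts were 3 and 9. A chlorophyll A-B binding probe (454_Contig10446) fell by 3.42 ± 0.75, and photosynthesis had 1 higher and 3 lower of 146 (1 and 2 adjusted over the list alone). Tubulin beta 8 (EST_FF381209) rose by 1.24 ± 0.23, 1 of 5 reference probes of 174 that rose (3 adjusted over the list alone). ELF4-like 4, a clock gene, rose by 0.85 ± 0.20 (JGIv7_cassava4.1_019570m) and 0.73 ± 0.19 (EST_Contig09795), the 2 calls among 17 clock probes (4 higher and 3 lower adjusted over the list alone).

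The remaining HN lists at 24 h had few calls, given as higher and lower, then adjusted over the list alone in brackets. They were senescence 3 and 4 of 39 (4 and 7), NAC 1 and 2 of 41 (1 and 4), lipid transfer 2 and 1 of 46 (3 and 1), and vascular 2 and 1 of 32 (5 and 2). Cell cycle had 1 and 3 of 121 (1 and 1), but 21 and 6 with slide as a block and 1 and 1 within slide 3. Others were ethylene 1 and 1 of 37 (2 and 6), phenylpropanoid 1 and 0 of 45 (1 and 0), protease inhibitors 0 and 1 of 28 (0 and 1) and ribosomal 0 and 1 of 11 (4 and 1). Camera called the ribosomal list higher (mean 0.33, adjusted p = 0.947 with an estimated correlation; 0.23 with slide as a block or within slide 3). That call was lost with the block (0.0959) and within slide 3 (0.0949). Camera called 7 lists only with slide as a block: cell cycle (mean 0.78, adjusted p = 0.000308) higher, and protease inhibitors (-0.55), NAC (-0.54), ethylene (-0.38), redox (-0.30), photosynthesis (-0.27) and abscisic acid (-0.17) lower. All but abscisic acid were also called within slide 3, where HN 24 h has 2 arrays. No flavonoid or salicylic acid probe passed with either adjustment. The count of 1606 was 4380 with slide as a block, 1362 within slide 3, 188 when only these groups were fitted, 5907 with array weights and 545 with no filter on dim probes. Leaving out HN 24 h replicates 1, 2 and 3 gave 3959, 841 and 539, leaving out HN control replicate 2 gave 555, and leaving out that control with HN 24 h replicate 1, chosen after the data were seen, gave 2504. The fit with slide as a block also leaves HN 24 h replicate 1 out of this change.

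**Figure D3:**
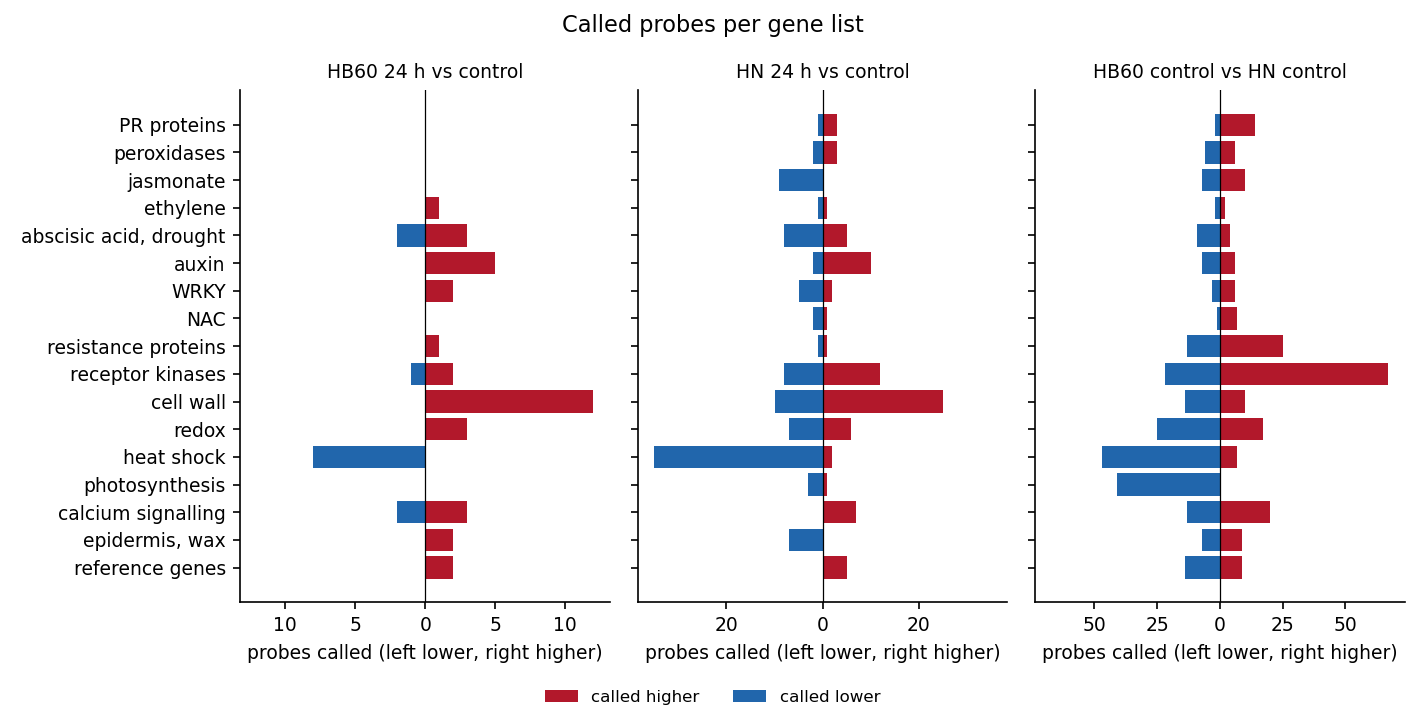
Bars count the called probes of 17 gene lists in 3 comparisons, lower to the left and higher to the right, each panel with its own linear axis. Heat shock has 8 and 35 lower at 24 h in HB60 and HN, and receptor kinases have 67 higher in HB60 controls than in HN controls.

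At 72 h in HN, 1 probe was called against the control, the undescribed sequence FGv7_scaffold06299_FGENESH5, well above background on the 3 infected arrays and on no control array (adjusted p = 0.00627). It was named after its value was seen, and 1891 probes had an unadjusted p under 0.05. Quantile normalization and the authors' values gave 2 calls, normexp and the fit within slide 3 gave 0, array weights gave 3017, and the count was 0 without HN control replicate 3 or HN 72 h replicate 1 or 3, 12 without HN 72 h replicate 2, and 2 without HB60 72 h replicate 2 or 3. Heat shock protein 21 (EST_Contig12518) lay at -0.40 ± 3.96 against 2.74 ± 1.39 in controls, with 1 infected array above background, and SAUR-like JGIv7_cassava4.1_026012m was not well above background in either group. Camera called 5 lists, each with adjusted p = 0.807 with an estimated correlation and no member passing with either adjustment: photosynthesis (mean 0.38), ribosomal (0.45), redox (0.18) and reference genes (0.19) higher, and flavonoid enzymes (-0.39) lower. These groups lie on 1 slide, so the values within slide 3 and with slide as a block are the same. Photosystem I subunit D-1 (EST_Contig04017), a photosynthesis member, differed by 0.64 ± 0.23 (adjusted p = 0.749), and leucoanthocyanidin dioxygenase (JGIv7_cassava4.1_010809m), an anthocyanin enzyme, by -0.92 ± 0.41 (adjusted p = 0.749).

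Between 24 h and 72 h, heat shock genes were among those that rose in HN. There 1695 probes were called, 985 higher and 710 lower at 72 h (595 and 692 with quantile normalization). Of 221 heat shock probes 32 rose and none fell (51 and 7 adjusted over the list alone). Their mean was 0.59 (camera adjusted p = 0.0012; adjusted p = 0.301 with an estimated correlation), and 0.60 within slide 3 or with slide as a block. Photosynthesis genes rose in 11 of 146 probes (32 adjusted over the list alone; mean 0.52, adjusted p = 0.852 with an estimated correlation; 0.64 within slide 3). Redox genes rose in 13 and fell in 6 of 243 (20 and 9 adjusted over the list alone). With slide as a block 71 redox probes rose and 9 fell, and within slide 3 the counts were 26 and 3. Cell wall genes rose in 15 and fell in 17 of 264 (23 and 27 adjusted over the list alone). In HB60 149 probes were called, 45 higher and 104 lower. Of 221 heat shock probes 6 were higher (14 higher and 1 lower adjusted over the list alone; list adjusted p = 0.358 with an estimated correlation and 0.112 by fry), and none passed with slide as a block. Lower were cell wall 8, auxin 4 and abscisic acid 3 (2 higher and 19 lower in the cell wall list alone). The cell wall mean in HB60 was -0.28 (adjusted p = 0.729 with an estimated correlation). It was 0.35 with slide as a block, where camera called the list in the opposite direction (adjusted p = 0.0363). The times share no slide in HB60, and with slide as a block 7 probes passed there against 6032 in HN, where 2054 passed within slide 3 and 133 when only these groups were fitted. The HB60 count was 75, 47 and 48 without HB60 24 h replicates 1, 2 and 3 and 57, 68 and 91 without the 72 h ones. The HN count was 5781, 796 and 454 without HN 24 h replicates 1, 2 and 3, 526, 649 and 894 without the 72 h ones and 2713 without HN control replicate 2. Camera called 11 lists in HB60 and 8 in HN for this interval, none of them with an estimated correlation. The fit with slide as a block gave 14 and 11, of which 8 and 4 were new, while 5 and 1 of the calls without the block were lost and the HB60 cell wall call reversed.

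Genes called at 24 h in one cultivar tended to differ in the same direction in the other. Of all 30080 probes 45.8% had the same direction in both. Of the 173 probes higher in HB60, 109 were also higher in HN, where independent lists would share 4.68, and of the 86 lower 28 were shared, against 2.27. None was called in opposite directions. Of the 813 probes higher in HN 566 were also higher in HB60, called or not, and of the 793 lower 540 were lower. The shared increases include xyloglucosyl transferase 33, the SAUR-like, PYR1-like 4 and LEA3 probes and the TIR-class gene 454_Contig05899. Across all probes the 24 h changes of the cultivars correlated at r = 0.138 and the 72 h changes at -0.155, over probes that are not independent replicates. No other split of the HB60 24 h and control arrays gave any call, so relabelling could hardly test the sharing. Of 100 relabellings of the arrays within each cultivar, the real one was the only one with as many as 137 shared calls. That number was 67, 56 and 47 without HB60 24 h replicates 1, 2 and 3, 67, 36 and 77 without HB60 control replicates 1, 2 and 3, and 90 without HN control replicate 3, and it was 104 within slides. Within a cultivar the 24 h and 72 h changes use the same controls. Their correlation across probes was 0.509 in HB60 and 0.347 in HN, where simulated unchanged groups gave a median of 0.516 (inner quantile interval -0.0139 to 0.823). Their covariance was 0.0811 and 0.0841 against a simulated median of 0.0575 (interval -0.00128 to 0.169). Both measures lay inside the simulated intervals, so no excess was shown. No call was shared between 24 h and 72 h in either cultivar, where independent lists would share 0 in HB60 and 0.0270 among increases in HN. The 3 controls cannot be split into parts of at least 2, so they cannot be excluded as the source of any excess. With slide as a block the HB60 changes rest on different controls, 2 at 24 h and 1 at 72 h, and their correlation is given below.

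**Figure D4:**
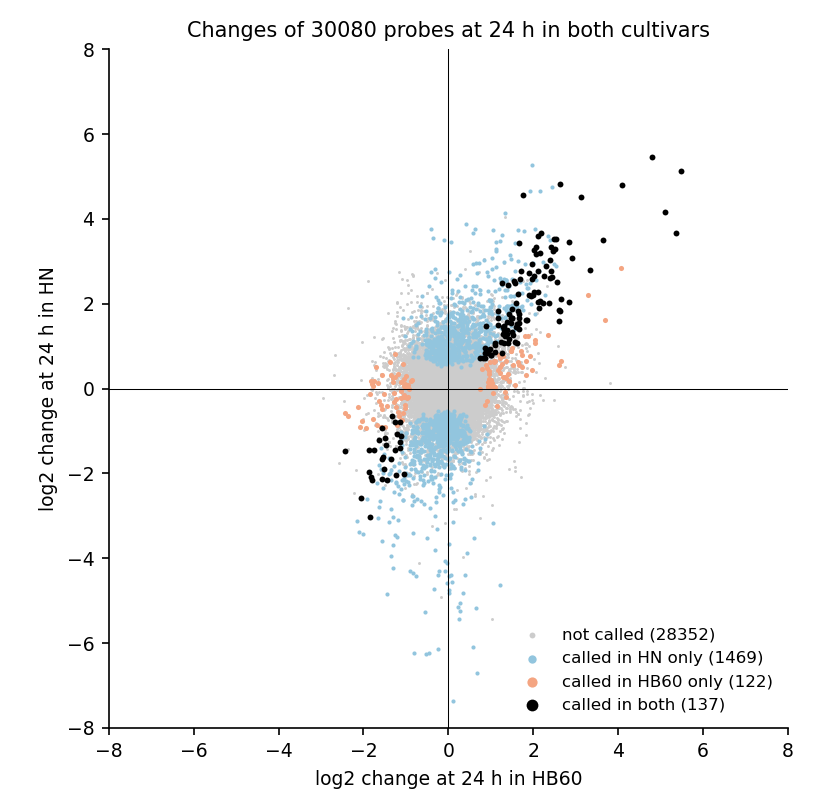
Each point is 1 of 30080 probes, with its log2 change at 24 h in HB60 on the horizontal and in HN on the vertical axis, coloured by where it was called. The 137 probes called in both lie in the quadrants of shared direction.

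The response itself differed between cultivars at 24 h for 4 probes, with 5713 at an unadjusted p under 0.05. Myb domain protein 73, a stress-related transcription factor (EST_Contig06563), rose by 2.43 in HN and differed by -0.46 in HB60, a difference of -2.88 ± 0.43 (adjusted p = 0.0465). A DUF1005 probe (454_Contig05813) rose by 4.55 in HN and 1.77 in HB60, the undescribed EST_Contig12419 rose by 2.75 in HN and differed by -0.40 in HB60, and a DUF604 probe (JGIv7_cassava4.1_023338m), not well above background on any HN 24 h array, fell by at least 2.13-fold in HN and differed by 0.36 in HB60. These 3 were named after their values were seen. WRKY 71 (454_Contig04946), 2.06 ± 0.36 higher in the HB60 response, did not pass (adjusted p = 0.0773). Camera called 7 lists at 24 h, each with adjusted p = 0.917 with an estimated correlation. The response was higher in HB60 for jasmonate (0.49), ethylene (0.46), protease inhibitor (0.45), phenylpropanoid (0.44) and WRKY (0.36) genes and lower for cell cycle (-0.69) and ribosomal (-0.51) genes. With slide as a block the means were 0.56, 0.76, 0.76, 0.28, 0.63, -1.28 and -0.49, and peroxidases (0.76), NAC (0.71) and senescence (0.47) were called only with the block. The phenylpropanoid call was lost with it (adjusted p = 0.332). No member of any list passed over all probes. Adjusted over the list alone, 25 heat shock probes were higher and 4 lower in the HB60 response, and 8 jasmonate, 4 epidermis and wax and 2 phenylpropanoid probes were higher. The count of 4 was 2563 with slide as a block, 7025 with array weights, 24 with normexp and 1 with quantile normalization. It was 1025 without HN 24 h replicate 1, 48 without HN control replicate 3, 37 without HN 72 h replicate 2, 11 without HB60 control replicate 3, 4 without HN 72 h replicate 1, 2 without HN 24 h replicate 2 and 1 without any other array.

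At 72 h no probe's response differed between cultivars by limma (1925 at an unadjusted p under 0.05; smallest adjusted p 0.767), while quantile normalization gave 1, slide as a block 3, array weights 3223 and the fit without HN 72 h replicate 2 gave 5. Camera called 6 lists, with adjusted p = 0.924 with an estimated correlation for redox genes and 0.891 for the others. The HB60 response was higher for flavonoid (0.82), ethylene (0.30), jasmonate (0.28) and receptor kinase (0.11) genes and lower for photosynthesis (-0.39) and redox (-0.22) genes. With slide as a block the means were 1.40, 0.06, 0.22, 0.09, -0.25 and -0.21, and 6 lists were called only with the block. The ethylene (adjusted p = 0.596) and receptor kinase (0.111) calls were lost with it. Leucoanthocyanidin dioxygenase (JGIv7_cassava4.1_010809m) had a difference of 1.88 ± 0.58 and did not pass (adjusted p = 0.767). Nor did ETHYLENE-INSENSITIVE3-like 1 (454_Contig04528), a transcription factor of ethylene signalling. It was not well above background on any HN 72 h array, so no size is given for its difference.

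The control comparison asks how the cultivars differ without infection. A cysteine-rich receptor-like kinase (JGIv7_cassava4.1_021581m) was at least 25.9-fold higher in HB60 (adjusted p = 3.84e-10), and wall-associated kinase 5, of a family that senses pectin, at least 23.3-fold (FGv7_scaffold07238_FGENESH99) and 15.6-fold (FGv7_scaffold07238_FGENESH102). A natural resistance-associated macrophage protein (EST_CAS03_041_E22.f), of a metal transporter family, was at least 49.2-fold higher. Basic pathogenesis-related protein 1 (EST_FF380833) was 3.71 ± 1.40 in HB60 and -0.45 ± 0.55 in HN (adjusted p = 0.00171). WRKY 70 (EST_CAS03_044_H21.f), a regulator in salicylic acid signalling, was at least 5.00-fold higher. Lower in HB60 were a lipid-transfer family probe (454_Contig12144), by at least 5717-fold, catalase 1 (454_Contig02189), which breaks down hydrogen peroxide, by at least 355-fold, drought-induced 21 (454_Contig14418), by at least 331-fold, and heat shock factor A2 (EST_DV445481), by at least 8.54-fold. All of these are signals of single probes. Sequence differences between the cultivars under the probes were not tested here, so probe binding stays open.

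Of 30080 probes 4565 differed, 2404 higher and 2161 lower in HB60, and 2805 by at least 2-fold. Receptor kinases had 67 higher and 22 lower of 341 (79 and 27 adjusted over the list alone; 27.3 higher by chance, hypergeometric adjusted p = 1.38e-10). Their mean was 0.39 (camera adjusted p = 0.00472; adjusted p = 0.635 with an estimated correlation) or 0.58 with slide as a block (1.6e-05). Resistance proteins, intracellular pathogen sensors, had 25 higher and 13 lower of 88 (34 and 16 adjusted over the list alone; hypergeometric adjusted p = 1.86e-07). Their mean was 0.37 (adjusted p = 0.863 with an estimated correlation), 0.50 with slide as a block. Pathogenesis-related proteins had 14 higher and 2 lower of 63 by either adjustment (hypergeometric adjusted p = 0.00334), mean 0.57 (adjusted p = 0.863 with an estimated correlation), but 0.14 with slide as a block (camera adjusted p = 0.469). Photosynthesis genes had 41 lower and none higher of 146 (61 lower and 1 higher adjusted over the list alone; hypergeometric adjusted p = 4.45e-13). Their mean was -0.62 (adjusted p = 0.863 with an estimated correlation), -1.13 with slide as a block. With quantile normalization 27 were lower. Photosystem II subunit X (EST_Contig06345) was -0.75 ± 0.49 against 0.92 ± 0.63. Heat shock genes had 7 higher and 47 lower of 221 (10 and 54 adjusted over the list alone; hypergeometric adjusted p = 1.84e-10). Their mean was -0.53 (adjusted p = 0.27 with an estimated correlation), -0.55 with slide as a block (0.0596). Protease inhibitors had 1 higher and 6 lower of 28 (2 and 8), mean -0.35 (adjusted p = 0.863 with an estimated correlation), -0.98 with slide as a block.

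The other lists, as higher and lower in HB60 and then adjusted over the list alone, had calls in both directions or few, and with normexp WRKY (5 and 6), cell wall (11 and 10) and receptor kinase (41 and 27) counts shifted. Redox had 17 and 25 of 243 (20 and 29), calcium 20 and 13 of 217 (23 and 14), jasmonate 10 and 7 of 75 by either adjustment, cell wall 10 and 14 of 264 (8 and 8), reference genes 9 and 14 of 174 by either, epidermis and wax 9 and 7 of 73 (11 and 9), and auxin 6 and 7 of 148 (2 and 1). Abscisic acid and drought had 4 and 9 of 99 by either, peroxidases 6 and 6 of 58 by either, WRKY 6 and 3 of 77 (5 and 3), NAC 7 and 1 of 41 by either, phenylpropanoid 3 and 5 of 45 by either, and cell cycle 3 and 4 of 121 (3 and 1). Senescence had 3 and 3 of 39 (4 and 3), vascular 3 and 3 of 32 (3 and 4), lipid transfer 2 and 3 of 46 (1 and 2), clock 2 and 2 of 17 by either, ethylene 2 and 2 of 37 (0 and 0), flavonoid 0 and 3 of 27 by either, ribosomal 0 and 3 of 11 by either, and salicylic acid 3 and 0 of 6 by either. Lipoxygenase 2 (JGIv7_cassava4.1_029416m), an enzyme of jasmonate synthesis, was at least 7.89-fold higher in HB60. NPR1-like protein 4 (FGv7_scaffold06299_FGENESH4), a salicylic acid receptor relative, was 2.73 ± 0.31 higher with 2 HN arrays above background. With slide as a block 1419 probes passed and with array weights 15616, and no slide holds control plants of both cultivars, so no within-slide value can be had. Camera called 7 lists only with the block, redox (mean -0.79, adjusted p = 3.55e-06; -0.18 and 0.222 without) with 1 probe higher and 17 lower. The others were ribosomal (-0.83), lipid transfer (-0.82), peroxidase (-0.63), cell cycle (0.74), clock (0.58) and salicylic acid (0.92). The 2 arrays that link the cultivars carry all of these. The count was 2722 and 2470 without HB60 control replicates 1 and 2 and 2646 without HN control replicate 2.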

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

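The tests of slide, of the change without 1 array, of harvest hour, of HN control replicate 2, of a raised level in HN controls and of sequence differences were chosen only after the result was seen.

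The 24 h response differed between the cultivars, by the test of the difference, for 4 probes. These were 454_Contig05813 (-2.78, HB60 minus HN), EST_Contig12419 (-3.15), JGIv7_cassava4.1_023338m (3.08, with the HN 24 h group not well above background, so its size is not a measured one) and myb domain protein 73, EST_Contig06563 (-2.88). Of 100 relabellings of the arrays within each cultivar, 12 gave 4 or more, so chance cannot be excluded. The highest other count was 1260, from the relabelling that exchanges all HN labels and so adds the responses. All relabellings here used the fit without slide. With slide as a block far more probes passed, as given above, and that fit was not relabelled. Camera called 7 lists with mean differences of 0.44 (phenylpropanoid), 0.49 (jasmonate), 0.46 (ethylene), 0.36 (WRKY), -0.69 (cell cycle), 0.45 (protease inhibitors) and -0.51 (ribosomal). Of the relabellings 62 gave 7 or more lists (highest 16), so chance cannot be excluded.

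At 72 h camera called 6 lists with mean differences of 0.82 (flavonoid), 0.28 (jasmonate), 0.30 (ethylene), 0.11 (receptor kinases), -0.22 (redox) and -0.39 (photosynthesis). Of 100 relabellings 74 gave 6 or more lists (highest 18), and all 100 gave at least the 0 probes found by limma (highest other 6; 1925 probes at an unadjusted p under 0.05), so chance cannot be excluded. None of these 13 list differences was called with an estimated correlation.

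For the other comparisons the 10 splits of 6 arrays are too few for a share under 0.05. The real probe counts and the highest of the other splits were 259 and 0 (HB60 24 h), 0 and 0 (HB60 72 h), 1606 and 6 (HN 24 h), 1 and 1 (HN 72 h), 149 and 0 (HB60 72 h against 24 h), 1695 and 13 (HN 72 h against 24 h) and 4565 and 11 (controls). As many probes came from 1, 10, 1, 4, 1, 1 and 1 splits in that order. For camera lists the real and highest other counts were 7 and 12, 3 and 14, 5 and 13, 5 and 14, 11 and 11, 8 and 15, and 6 and 15, with as many from 8, 7, 8, 5, 2, 5 and 7 splits. Other groupings of the same arrays gave as many lists in each of these comparisons, so chance cannot be excluded for the list counts.

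The first pattern weighed is the 137 calls shared by the cultivars at 24 h. Only 1 of 100 relabellings, the real one, gave as many (highest other 0). No other split of the HB60 24 h and control arrays gave any call. Other relabellings could therefore hardly share calls, and this test does not decide on chance. Within slides, the smaller ratio of the shared probes' median change to the pooled one was 0.966, with 137 of 137 in the same direction. The within-slide fits leave out only HB60 control replicate 3 and HN 24 h replicate 1. The probes were chosen for their change with all arrays, so a low ratio was unlikely in advance and the test does not decide on slide. The test of a single array written before the result was seen found as few as 35 still called in both cultivars without HB60 control replicate 2, the value that dependence on a single array would give. Leaving out an array also lowers the power, and the lowest ratio of the median change without 1 array was 0.957, a measure computed only after that count had been seen, so the size of the change held without any 1 array while the number of calls depended on single arrays. The 0.966 above is also the ratio without HB60 control replicate 3, so these tests are not separate, and both use probes chosen with all arrays. The clock probes leave harvest hour open, since their median absolute change lay at the 60.95th percentile of matched random sets in HB60 and the 96.32nd in HN, and a shared response to inoculation, puncture or hour may underlie the pattern. The labels do not state the hour of inoculation. If it was the same for all plants, another hour for the controls would show at 72 h too. Probes called higher at 24 h include shared ones. Their 72 h medians were 0.16 in HB60 (1.58 at 24 h) and 0.23 in HN (1.28). Those called lower had -0.24 (-1.34) and -0.14 (-1.17). On that condition these values argue against the hour of the controls as the whole cause.

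The second pattern is the 35 heat shock probes lower in HN at 24 h. On slide 3 alone their median change was -4.48, and without HN control replicate 2 the number still called was 24. The probes were chosen for their change with all arrays, so neither value decides on slide or on that array. All 221 heat shock probes, which were not chosen in this way, had a mean change of -0.73 within slide 3 and -0.72 over all arrays. That argues against slide as the whole cause of the list's fall. A raised level in the HN controls alone would leave HN 72 h as low as 24 h, but its median was -0.79 against the controls (arrays -1.43, 0.93 and -1.83, against -4.11 to -4.24 at 24 h). Every HB60 array, controls included, also lay below the HN controls on these probes, from -0.75 to -2.96. A raised level in the HN controls as a part of the fall therefore stays open, and the probes were chosen for being high in those controls. A lower level at 24 h in HN may be a response, while the hours of inoculation and harvest and the temperature of the plants, which the labels do not give, stay open. If all plants were inoculated at the same hour of day, another hour for the controls would lower these probes at 72 h as well. On that condition the 72 h arrays above argue against the hour of the controls as the whole cause.

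The third pattern is the 102 probes of the receptor kinase, resistance and pathogenesis-related lists that were higher in HB60 than HN controls (37 were lower). With slide as a block their median difference was 1.66 (1.84 without), but slide 2 alone holds both cultivars, with 1 HN array, so slide stays open. In infected plants 91 at 24 h and 93 at 72 h were higher in all 3 HB60 than all 3 HN arrays, where 16.1% and 20.9% of all probes were and chance gives 5% in this direction, which argues against conditions of the control plants alone. The difference changed with infection for 0 of the 102, by tests that called 4 and 0 of all probes, so this count tells nothing of sequence differences under the probes, which stay open. A cultivar difference in expression may be a candidate explanation, and the data cannot separate it from slide or probe binding.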

How the results depend on the processing

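The percentile over detected probes, the pair of arrays left out together and the hypergeometric test were chosen only after the result was seen. The mean over a gene's probes was not run, because each ID has 1 probe.

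Of 376 named genes and comparisons, 197 were called, and none of these reversed direction under any alternative. The naming rule picks mostly large called changes, so a reversal was unlikely in advance. Over all alternatives, called values stayed called 5081 times and missed the threshold 895 times, and uncalled ones passed it 139 times. Fits that leave out arrays make up 3085 and 529 of the called values. Of the 197, 77 missed the threshold in fits of only the groups compared and 66 with no filter on dim probes. Within one slide 68 stayed called and 38 missed it. The cause of each change below was not tested, except that leaving out arrays or fitting fewer groups lowers the degrees of freedom and the filters change the number of probes tested. Slide as a fixed block also changes which arrays are compared.

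Array weights (0.196 to 8.03) gave 7744 calls in HB60 at 24 h, 2264 at 72 h, 5907 in HN at 24 h, 3017 at 72 h, 570 and 6638 for 72 h against 24 h in HB60 and HN, 7025 and 3223 for the response differences at 24 h and 72 h, 15616 for controls and 1097 shared. HB60 control replicate 2 (8.03) and HN control replicate 3 (6.10) had the largest weights, so weighted control means rest mostly on 1 array per cultivar. Slide as a fixed block gave 6 in HB60 at 72 h, 4380 in HN at 24 h, 7 and 6032 for 72 h against 24 h, 2563 and 3 for the response differences, and 1419 for controls, and it turned the correlation of the 24 h and 72 h changes in HB60 from 0.509 to -0.0414. With the fixed block the HB60 24 h change rests on the 2 controls of slide 1 and the 72 h change on the 1 control of slide 2. These changes then share no control, whose loss alone would lower the correlation. Slide as a random block (correlation 0.299) gave 2662 in HN at 24 h, 23 and 3149 for 72 h against 24 h, and 1953 for controls. Within one slide HB60 at 24 h had 652 and HN at 72 h 0. The fixed block and the fit within slide 3 both leave HN 24 h replicate 1 out of the HN changes at 24 h. Without that array and with no block, HN at 24 h had 3959 and HN for 72 h against 24 h had 5781.

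With no filter on dim probes the counts were 82 in HB60 and 545 in HN at 24 h, 65 and 573 for 72 h against 24 h, 2 for the 24 h response difference, 2810 for controls and 49 shared. With probes above background on all arrays they were 0 in HN at 72 h, 97 in HB60 for 72 h against 24 h and 9 for the 24 h response difference. Fits of only the groups compared gave 188 and 0 in HN at 24 h and 72 h, 133 in HN for 72 h against 24 h, 30 for the 24 h response difference, 2169 for controls and 37 shared.

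In HN at 72 h quantile normalization gave 2, normexp 0, the authors' processed values 2, and an intensity trend with robust variance 0. The 24 h response difference had 1 with quantile normalization, 24 with normexp, 1 with the authors' processed values and 2 with the percentile over detected probes, and the 72 h one had 1 with quantile normalization. At least 2-fold changes numbered 1076 in HN for 72 h against 24 h and 2805 for controls. The percentile over detected probes moved the median of all probes by -0.13 in HN at 72 h, -0.15 in HN for 72 h against 24 h and 0.10 in the 72 h response difference. Without HN control replicate 2 and HN 24 h replicate 1 together, HN at 24 h had 2504. The 58 list shifts of camera became 0 with an estimated correlation and 4 with fry.

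Leaving out each array in turn gave 45 to 431 in HB60 at 24 h, 0 to 0 at 72 h, 539 to 3959 in HN at 24 h, 0 to 12 at 72 h, 47 to 207 and 454 to 5781 for 72 h against 24 h, 1 to 1025 and 0 to 5 for the response differences, 2470 to 5714 for controls, 46 to 66 list shifts, 36 to 187 shared calls, and correlations of 0.382 to 0.637 in HB60 and 0.212 to 0.552 in HN.

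With the replicate block the counts were 192, 0, 1439, 1, 121, 1628, 2, 0 and 4349 for the 9 comparisons in the order above, with 60 list shifts. The correlation of residuals between samples of like replicate number ran from -0.341 to 0.241. No pairing by replicate number was seen, but 3 arrays per group cannot exclude it. Between 40.6% and 56.7% of probes per array were well above background, which limits what dim probes can show.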

Other observations

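The enrichment of single descriptions, over 1044 descriptions with adjusted p, was chosen only after the result was seen.

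In HN at 24 h, 6 of 8 probes of hydroxy methylglutaryl CoA reductase 1, an enzyme of isoprenoid synthesis, fell (adjusted p = 4.60e-06), as did 4 of 8 of the terpenoid cyclases (0.00358), 13 of 70 of the galactose oxidase/kelch repeat family (8.36e-06), 11 of 37 of the HSP20-like chaperones (1.91e-06) and 4 of 6 of glycosyl hydrolase 9C2 (0.00103). Of the phosphate-responsive 1 family 4 of 6 rose (0.00397). In HB60 at 24 h, 3 of 6 cellulose synthase family probes and 3 of 6 of glycosyl hydrolase family 32 rose (0.00193 each). In controls, 7 of 9 probes of receptor-like protein kinase 1 (0.000672) and 5 of 5 of wall-associated kinase 2 (0.0017) were higher in HB60, and 6 of 6 of NF-X-like 1 (0.000143) were lower. Whether probes of 1 description measure 1 gene is not known, so these counts are not of independent genes.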
